A study of Mus musculus with 8 samples.

How the data were processed

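Transcript abundance was measured by RNA-seq of total RNA from cultured ILC2s in 8 libraries, 4 treated with vehicle and 4 with SC-57461A. Per the submitters' processing notes, reads were processed with cutadapt 4.7 and FastQC and the genome build was mm10; the aligner, the counter, its strand setting and the annotation are not given in the sources used here. The deposited table, per the file headers, holds a raw count and an FPKM value for each gene in each library, together with gene coordinates and annotation terms. The counts are whole numbers with different totals per library. FPKM, which scales fragments by gene length and library total, was computed by the authors, and 0 columns of values were left unmatched to a sample. Of 25367 genes in the table, 24998 were given a symbol from GENCODE release M21 by Ensembl gene identifier, since the gene name column repeats the identifiers, and 1785 had a count of 0 in every library. Coordinates are those of the deposited table (mm10), counted from 1.

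Libraries were grouped by the treatment in the labels. The plan fixed before the data were examined named limma on log2(FPKM + 1) for the case of FPKM alone and edgeR for the case of deposited raw counts; counts were deposited, so edgeR is the main test and limma on FPKM an alternative. Counts were filtered with filterByExpr (15095 genes kept), scaled with TMM factors and tested with the quasi-likelihood test of edgeR 4.0.16 (two-sided, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. CPM values were scaled by TMM factors, except those of marker genes of other cell types that are said to be in a library set and those of Gzmb and Zap70, which use library totals. Total counts were 47376196 to 71155654 per library, so that a count of 3, the most that a count of 0 allows, is 0.0422 to 0.0633 CPM. The 28 pairs of libraries, within and across the treatments, differed by a chi-square per degree of freedom of 16.7 to 583, where a repeat deposit would give about 1 or less, so no library was a repeat deposit of another. Each model was run on its own simulated counts, drawn from real means and library sizes with the spread of that model's fit. Of the genes, 200 were changed, drawn only from those above a floor of mean count. For edgeR without library set, the counts had 1 mean per gene over all libraries, so they held no library sets. That fit recovered 1.52%, 50.7% and 91.0% of genes changed by 0.5, 1 and 2 on the log2 scale (14589 genes in the fit, with 4.95% of the calls unchanged genes). The set-adjusted model, on counts with a mean per library set, recovered 60.6%, 89.6% and 100% (14750 genes, 7.73% of the calls).

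Library sets were read from the summed FPKM of each library, which parts the 8 libraries into 4 and 4 and crosses the treatments. The models with library set as a term (set-adjusted), the fits of either set alone and the transcript length offset were added after the data had been examined. The length offset was a spline with 5 degrees of freedom of each library's counts on the longest GENCODE M21 transcript of each gene.

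The 34 gene lists covering the pathway of the compound, ATP handling, ILC2 functions, other cell types, metabolism, stress and the cell cycle were fixed before the data were examined. Lists with at least 5 tested members were tested with camera (limma 3.58.1, log2 CPM with a prior count of 2, preset correlation 0.01), adjusted over 33 lists, beside camera with an estimated correlation and fry. With an estimated correlation 3 of the 18 calls held: cholesterol biosynthesis, the amino acid and integrated stress response, and p53 targets. Several genes stand in 2 lists. Gene ontology and KEGG terms with 10 to 500 tested genes, from the deposited table, were tested with a one-sided Fisher's exact test against the genes tested, for a direction with at least 20 called genes; 9 lower genes were too few. Named genes are those past the threshold with no overlap between the treatments, a mean FPKM of at least 5 in the higher group and an ordinary symbol (the 12 largest rises and, of 12 allowed, the 6 falls that qualified), 15 genes of the pathway and of ILC2s fixed in advance, and up to 4 members with the smallest p of each list that held a called gene. Other list members and genes given as examples were chosen after their values were seen. Some single-gene results are not reported here.

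Alternatives covered other scalings and filters, DESeq2 1.42.0, limma on FPKM with several settings, the replicate number as a block, and leaving out each library in turn. Near-identical copies were found by aligning transcripts with BLAST 2.17.0 (at least 95% identity over at least 50% of the transcript). Tables were handled and plots drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.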

Results

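RNA-seq profiles were obtained from cultured mouse group 2 innate lymphoid cells (ILC2s), lymphocytes without antigen receptors that release the cytokines IL-5 and IL-13. The cells had been sorted from the large intestine of C57BL/6 mice and grown for 5 days with IL-2, IL-7, IL-25 and IL-33, each at 10 ng/mL. They then received either vehicle or SC-57461A for 16 hours. SC-57461A inhibits leukotriene A4 hydrolase, the enzyme that makes the lipid mediator leukotriene B4 (LTB4). There were 4 libraries per treatment, with 47376196 to 71155654 counts and 17759 to 19223 genes with at least 1 count in each. The labels do not say that the 4 replicates came from separate animals or cultures, so all p-values measure only the spread between these libraries, which may be technical. The vehicle libraries held 50313937 to 71155654 counts and the SC-57461A libraries 47376196 to 52564876.

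The 8 libraries fell into 2 sets of 4 that crossed the treatments. Set A held vehicle replicates 1 and 2 and SC-57461A replicates 2 and 3, with FPKM values summing to 390628 to 428541 per library. Set B held vehicle replicates 3 and 4 and SC-57461A replicates 1 and 4, with sums of 316414 to 336044. The first principal component of log2 CPM carried 61.2% of the variance and parted the sets, and the second, with 10.2%, parted the treatments. Transcripts shorter than 1 kb supplied 11.6% ± 1.05 of the counts in set A and 6.61% ± 0.616 in set B (SD, n = 4 libraries of both treatments). Summed FPKM, from which the sets were read, itself rises with the share of short transcripts, so this contrast is not independent of it. Each treatment had 2 libraries in each set, so values from either set alone stand beside the pooled ones. The sets were recognised after the data had been examined, and a model that holds the library set, called the set-adjusted model, was added then.

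**Figure D1:**
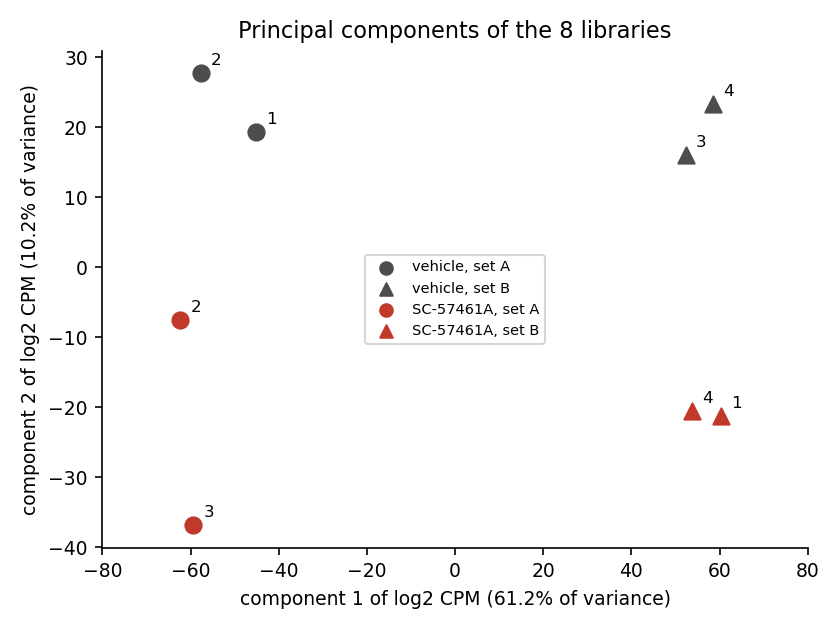
Each point is 1 of the 8 libraries on the first and second principal components of log2 CPM (axes in component units), with colour for treatment, shape for library set and the replicate number beside it. The first component (61.2% of the variance) parts set A from set B, and the second (10.2%) parts SC-57461A from vehicle.

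Set A libraries also held low counts of marker genes of other intestinal cell types, and the source of these counts was not tested. Lyz2, a lysozyme of macrophages and neutrophils, had 851 to 1607 counts in each set A library and 0 in each set B library. The neutrophil gene S100a9 had 83 to 139 counts against 0, and Cdh5, an endothelial cadherin, had 85 to 175 against 0. A count of 0 allows up to 3 counts, or 0.0422 to 0.0633 CPM in the libraries of set B, counting error only. Lyz2 lay at similar levels in both treatments, with a mean of 23.3 CPM in the vehicle libraries of set A and 24.6 CPM in the SC-57461A libraries of set A. The epithelial genes Krt8 and Krt19 (keratins) and Muc2 (intestinal mucin) differed. They had 352 to 609, 344 to 423 and 221 to 277 counts in the SC-57461A libraries of set A, against 50 to 152, 49 to 109 and 12 to 21 counts in the vehicle libraries of set A. In set B, Krt8 and Krt19 were at 0 in each library and Muc2 had 2 to 14 counts in SC-57461A and 0 in vehicle. These genes were picked out after their values were seen.

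**Figure D2:**
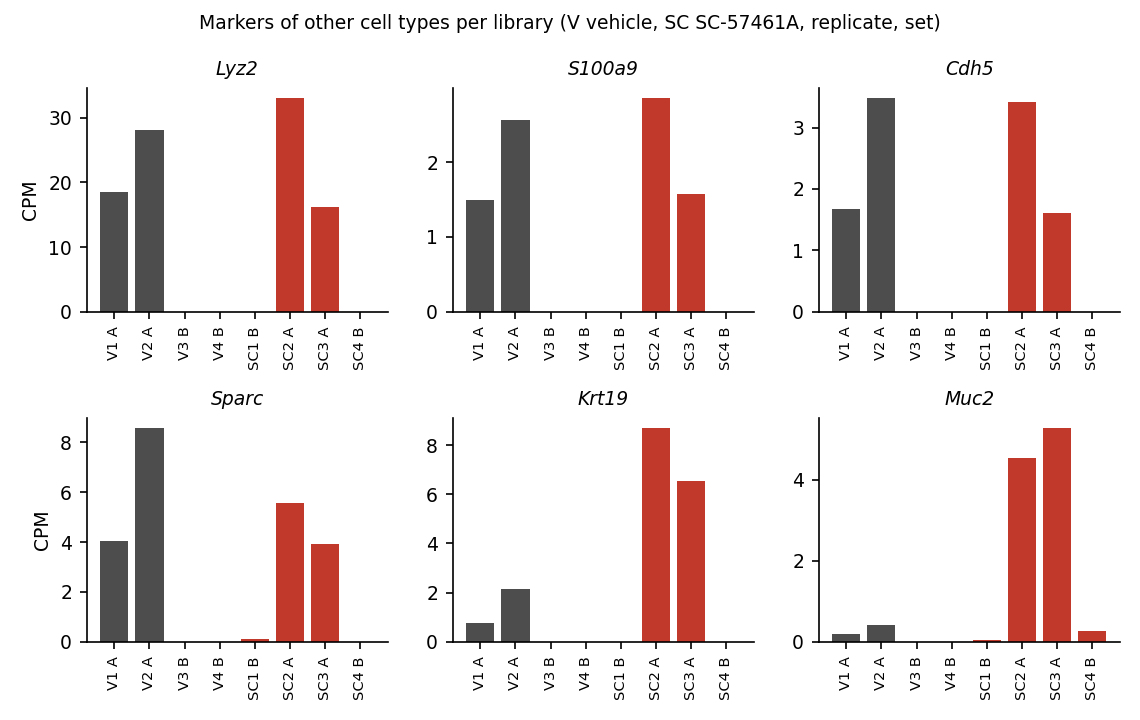
Bars give CPM (counts scaled by the library total) of 6 marker genes of other cell types in each of the 8 libraries, labelled by treatment, replicate and library set. Lyz2, S100a9 and Cdh5 are at 0 in the 4 libraries of set B, and Krt19 and Muc2 are highest in the 2 SC-57461A libraries of set A.

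The comparison of SC-57461A with vehicle asked which transcripts change in ILC2s that receive this inhibitor of leukotriene A4 hydrolase. LTB4 itself was not measured. Genes of cholesterol synthesis rose together. Of 24 tested members of that list, 17 were higher with SC-57461A over all genes tested, 22 were higher adjusted over the list alone, and none was lower, with a median log2 fold change of 1.33 (2.51-fold). Hmgcs1, which makes HMG-CoA at the entry of the pathway, rose from 78.7 ± 11.3 to 363 ± 47.3 CPM (mean ± SD, n = 4). Scd1, which introduces the double bond of oleate, rose from 12.4 ± 1 to 75.2 ± 12.8 CPM, and the immediate early transcription factor Fos fell from 21.4 ± 1.73 to 7.25 ± 0.938 CPM.

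Members of the cholesterol list rose at many steps of the pathway. Hmgcs1 (ENSMUSG00000093930, chromosome 13, 119690462 to 119708086 in mm10) had a log2 fold change of 2.21 ± 0.15 (SE, edgeR adjusted p = 0.000298), 2.23 in set A and 2.19 in set B. Acat2, which supplies acetoacetyl-CoA, rose by 1.73 (edgeR adjusted p = 0.00614). Among the enzymes that turn mevalonate into isoprenoid units, Mvk rose by 1.54, Mvd by 1.83, Idi1 by 1.98 and Fdps, farnesyl diphosphate synthase, by 1.85. Fdft1, which makes squalene, went from 39.4 ± 1.31 to 123 ± 7.31 CPM and Sqle, which oxidises it, rose by 1.26. Cyp51, which demethylates lanosterol, went from 66 ± 4.6 to 256 ± 28.3 CPM and Msmo1, the next methylsterol oxidase, from 32.1 ± 4.45 to 129 ± 14.7 CPM. Insig1, which retains the sterol sensor complex in the endoplasmic reticulum, rose by 1.37 and the sterol carrier Stard4 by 0.97. Srebf2, the transcription factor of the pathway (0.41, adjusted p = 0.77), did not pass in the edgeR fit over all genes. The smallest change of the list was that of Ebp, 0.39.

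Cholesterol synthesis genes passed camera as a set (adjusted p = 8.68e-60; adjusted p = 0.0006 with an estimated correlation; 9.66e-69 to 0.000714 over 21 alternatives). The list's median log2 fold change was 1.35 in set A and 1.29 in set B, and for 21 of the 24 genes all 4 SC-57461A libraries lay above all 4 vehicle libraries. In the set-adjusted model 24 of 24 passed. The deposited annotation gave the same theme, in terms that overlap one another: sterol biosynthetic process held 12 of its 23 tested genes among the 41 higher genes where 0.0625 would fall by chance (one-sided Fisher's exact test, adjusted p = 8.24e-23). Terpenoid backbone biosynthesis held 10 of 29 and biosynthesis of unsaturated fatty acids 5 of 26. Mvd overlaps the protein-coding gene Gm20388 on the opposite strand and Hmgcs1 an antisense gene, Fdps overlaps the protein-coding gene Gm43738 on the same strand, and Acat2 has a near-identical copy, Acat3 (97.7% identity). The strand of counting is not given in the sources used here, so the share of each partner in these counts is uncertain.

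**Figure D3:**
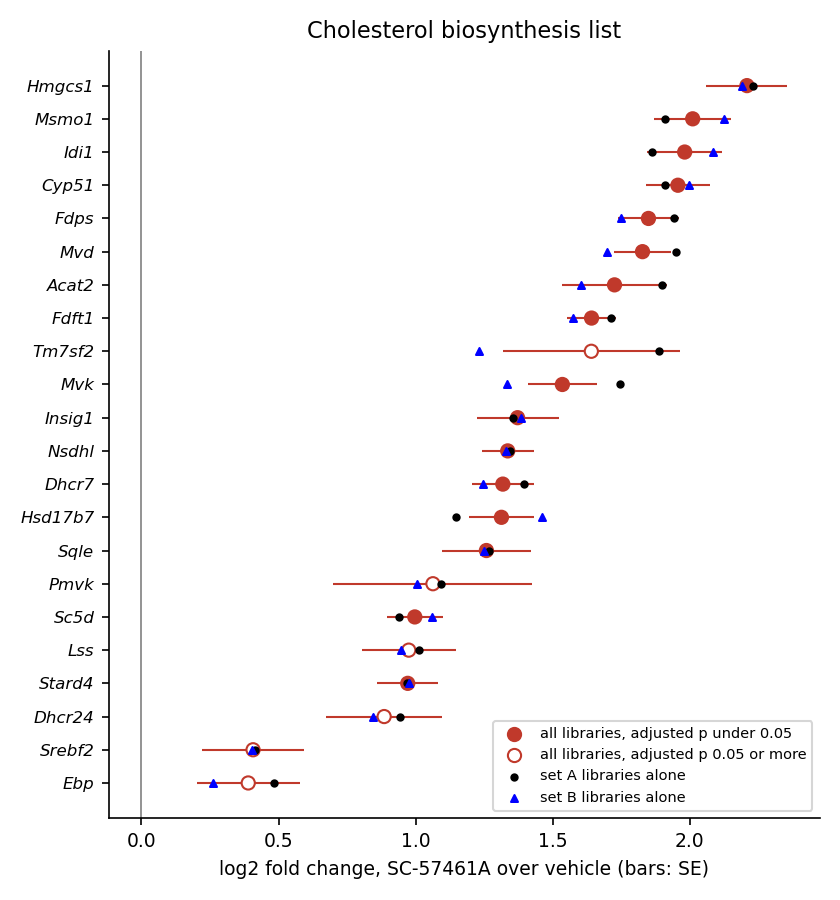
Large points give the log2 fold change, SC-57461A over vehicle, of 22 of the 24 tested genes of the cholesterol biosynthesis list with SE bars, filled where the edgeR adjusted p is under 0.05, and small points give the changes from the libraries of set A or set B alone. The changes run from 0.39 (Ebp) to 2.21 (Hmgcs1).

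Genes that build and desaturate fatty acids were also among the largest changes. Scd1 (ENSMUSG00000037071, chromosome 19, 44394451 to 44407709) rose 6.07-fold (log2 2.60 ± 0.15 SE, edgeR adjusted p = 0.000117; set A 2.44, set B 2.74). Fads2, a desaturase of polyunsaturated fatty acids (ENSMUSG00000024665, chromosome 19, 10064164 to 10101503), went from 18 ± 2.14 to 76.9 ± 4.6 CPM, and Scd2 from 378 ± 35.2 to 886 ± 151 CPM (adjusted p = 0.00802; past in 33 of 41 alternatives, up to 0.284). Acsl3, which activates fatty acids and overlaps Utp14b on the same strand, rose by 0.94 (adjusted p = 0.0365; past in 21 of 41 alternatives, log2 0.78 to 1.04, adjusted p up to 0.46). The elongase Elovl6 rose by 1.02 and Acss2, which makes acetyl-CoA from acetate, by 1.10; these 2 genes lie outside the fixed rule and were chosen after their values were seen. The list of fatty acid uptake, storage and oxidation was not called by camera: 3 of 39 tested members were higher (Scd1, Scd2 and Acsl3), 3 adjusted over the list alone, none was lower, the median was 0.014 and camera gave an adjusted p of 0.133. The fry test gave an adjusted p of 0.0509, and 0.00544 in the set-adjusted model (higher).

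The largest falls were in genes of several kinds. Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273) fell by 1.56 on the log2 scale (SE 0.13, edgeR adjusted p = 0.000878; set A -1.45, set B -1.67), and Egr1, another immediate early transcription factor, went from 142 ± 6.98 to 86.6 ± 4.48 CPM (adjusted p = 0.0137; past in 33 of 41, up to 0.345). Txnip, which binds thioredoxin and limits glucose uptake, went from 109.6 ± 4.77 to 67.3 ± 1.98 CPM (adjusted p = 0.0102; past in 33 of 41, up to 0.372); it overlaps the antisense gene Gm15441. Peg10, an imprinted gene derived from a retrotransposon, went from 565 ± 41.8 to 298 ± 42.8 CPM (adjusted p = 0.0253; past in 23 of 41 alternatives, log2 -1.03 to -0.82, adjusted p up to 0.332), the semaphorin Sema4a from 32.6 ± 3.05 to 18.1 ± 1.01 CPM (past in 35 of 39) and Lrrc75b from 34.8 ± 0.364 to 19.6 ± 0.366 CPM. Of 28 tested immediate early genes, 2 were lower over all genes, and 5 were lower and 3 higher adjusted over the list alone. The median of the list was -0.083 (set A -0.055, set B -0.16) and camera gave an adjusted p of 0.0485, with adjusted p = 0.625 with an estimated correlation. The set-adjusted model called 7 lower (Fos, Fosb, Fosl2, Egr1, Ier2, Dusp1 and Zfp36) and 2 higher (Myc 0.59 and Maff 0.60).

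Ighm, the constant region of the immunoglobulin mu heavy chain (ENSMUSG00000076617, chromosome 12, 113418558 to 113422730), rose from 3.67 ± 0.54 to 22.3 ± 1.39 CPM (log2 2.60 ± 0.14 SE, edgeR adjusted p = 0.000117; set A 2.65, set B 2.57). Other B cell transcripts did not rise with it: Cd79b, part of the B cell receptor, stood at 14.7 ± 1.4 and 15.8 ± 0.937 CPM, and the light chain gene Igkc had 0 to 71 counts per library. Of 6 tested B and plasma cell markers, Ighm alone was higher, also adjusted over the list alone. The median of that list was -0.082 and its mean 0.24, so the 2 differed in sign, and camera called it higher (adjusted p = 0.0485; adjusted p = 0.455 with an estimated correlation), though not in the set-adjusted model (adjusted p = 0.198; 0.0137 to 0.633 over 17 alternatives).

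Over all 15095 genes tested by edgeR, 41 were higher and 9 lower with SC-57461A at an adjusted p under 0.05, and 1008 had an unadjusted p under 0.05. Of the 50, 46 were protein-coding and 5 had a near-identical copy elsewhere, such as Gm3571 (a copy of Fdps) and Gm13502 (a copy of Idi1). For 926 genes (6.13%) the 4 values of one treatment lay above all 4 of the other. Chance would give 2.86% if all libraries were exchangeable, a value that ignores the library sets. The set-adjusted model called 427 genes higher and 377 lower, the 50 among them. The balance of rises and falls in that model depended on the fit: DESeq2 with library set called 653 higher and 851 lower, and leaving out 1 library gave 151 to 483 higher and 89 to 490 lower (400 and 479 without SC-57461A replicate 2). DESeq2 without that term called 117 higher and 78 lower. From set A alone 94 genes were higher and 28 lower, and from set B alone 87 and 16. The same 56 were higher and the same 10 lower in both, against 0.542 and 0.0297 for independent lists, and none was called in opposite directions. All 50 had the same sign of change in both sets, but they had been chosen by the fit over both; of all genes tested, 64.2% had the same sign. A test of the difference between the sets in the response to SC-57461A found 1 gene past the threshold, the antisense gene 2610206C17Rik, named only because it passed (0.23 in set A and 7.75 in set B), and 749 at an unadjusted p under 0.05.

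The target of the compound and the genes around it were then compared. Lta4h, which encodes leukotriene A4 hydrolase (ENSMUSG00000015889, chromosome 10, 93453396 to 93484896), was at 113 ± 7.16 CPM in vehicle and 109 ± 3.67 CPM in SC-57461A and did not pass (log2 -0.048 ± 0.091 SE, edgeR adjusted p = 0.999). Alox5, the lipoxygenase that makes leukotriene A4 (ENSMUSG00000025701, chromosome 6, 116410077 to 116461178), was at 5.85 ± 0.513 and 3.43 ± 0.401 CPM (log2 -0.77, adjusted p = 0.112; set A -0.72, set B -0.82) and was called lower in 12 of 28 alternatives, the set-adjusted model among them (adjusted p = 0.00875; 0.000221 to 0.481 over 28 alternatives). The high-affinity LTB4 receptor Ltb4r1 had 187 ± 23.6 and 152 ± 24.6 CPM (log2 -0.30, adjusted p = 0.799; 0.038 in the set-adjusted model; 0.00107 to 1 over 41 alternatives). Alox5ap, which presents arachidonate to the lipoxygenase, and Ltb4r2, the low-affinity receptor, were below 1 CPM in both treatments. The counts of Alox5ap followed the library sets, with 15 to 40 in each library of set A and 0 to 4 in each of set B. The myeloid genes Lyz2 and S100a9 were also higher in set A, and whether ILC2s or other cells supplied the Alox5ap counts was not tested. Ltc4s, with 0 to 7 counts per library, was too low to test. Of 24 tested leukotriene and prostanoid genes none was higher or lower over all genes, and 1 was lower adjusted over the list alone. The median was -0.018 and the mean 0.0011, opposite in sign, and camera did not call the list (adjusted p = 0.171). The fry test called it lower (adjusted p = 0.0477; 0.0079 in the set-adjusted model). Alox5, Ltb4r1 and Ggt1 were lower and Abcc1 higher in the set-adjusted model.

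In the fixed list of extracellular ATP and adenosine handling, 1 member passed the pooled test, and it encodes a mitochondrial enzyme. Ak4, a mitochondrial adenylate kinase (ENSMUSG00000028527, chromosome 4, 101419277 to 101466995), rose from 13.2 ± 1.73 to 33 ± 2.9 CPM (log2 1.32 ± 0.13 SE, edgeR adjusted p = 0.00226; set A 1.27, set B 1.36). Entpd1, the ectoenzyme that hydrolyses extracellular ATP and ADP (ENSMUSG00000048120, chromosome 19, 40612366 to 40741602), was at 26.4 ± 2.12 CPM in vehicle and 18.4 ± 0.883 in SC-57461A (log2 -0.52 ± 0.096 SE). It did not pass over all genes (adjusted p = 0.107) and did in the set-adjusted model (adjusted p = 0.0055; 7.47e-06 to 0.736 over 39 alternatives). The adenosine receptor Adora2a had 15.5 ± 0.218 and 8.85 ± 1.63 CPM (log2 -0.81, adjusted p = 0.0667; 0.00305 in the set-adjusted model; 2.59e-07 to 0.367 over 39 alternatives). Nt5e, which makes adenosine from AMP (0.12), the ATP-release channel Panx1 (0.079) and the ATP-gated channel P2rx7 (-0.53, under 1 CPM) did not pass in either model. Of 31 tested members 1 was higher and none lower over all genes, 1 was higher and 2 were lower adjusted over the list alone, the median was -0.0098 (set A -0.023, set B 0.0038), and camera gave an adjusted p of 0.34. No metabolite was measured, so these values concern transcripts alone.

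**Figure D4:**
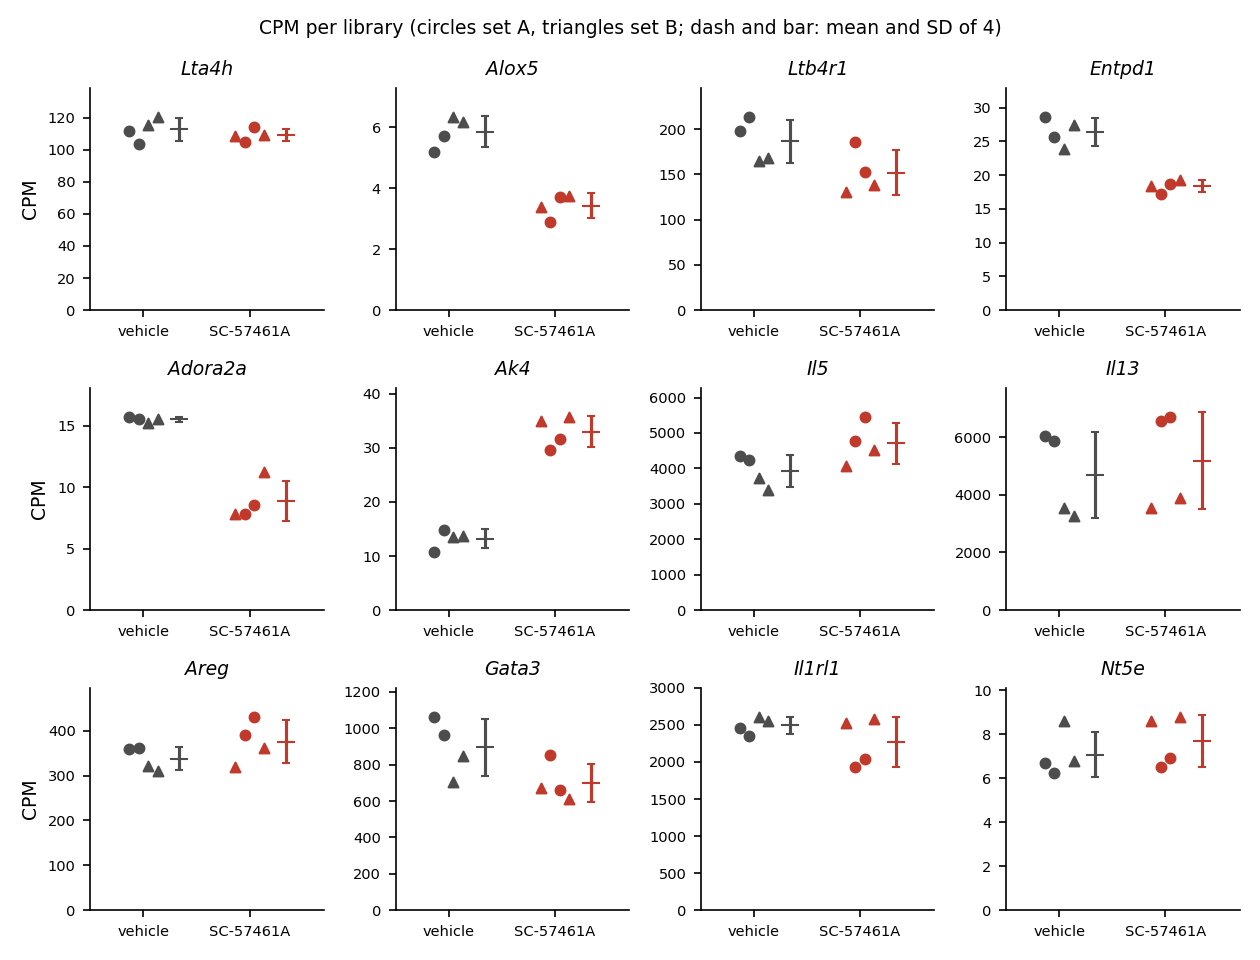
Points give CPM (scaled by TMM factors) of 12 genes in each library, circles for set A and triangles for set B, with the mean and SD of the 4 libraries of each treatment beside them. Ak4 lies higher and Alox5, Entpd1 and Adora2a lie lower in all 4 SC-57461A libraries than in all 4 vehicle libraries, while Lta4h overlaps and Il13 parts by library set.

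ILC2 cytokines and identity genes did not pass singly in the pooled fit. Il5 had 3923 ± 452 CPM in vehicle and 4705 ± 579.8 in SC-57461A (log2 0.26, edgeR adjusted p = 0.772; 0.0382 in the set-adjusted model; 0.00373 to 1 over 41 alternatives). Il13 stood at 4681 ± 1484 and 5179 ± 1686 CPM (log2 0.15, adjusted p = 0.999) and differed by 0.82 on the log2 scale between set A and set B. Areg, the epidermal growth factor family ligand amphiregulin (0.15), and Il1rl1, the IL-33 receptor (-0.14), did not pass in either model. Gata3, the transcription factor that defines the lineage, had 895 ± 155 and 699 ± 105 CPM (log2 -0.36, adjusted p = 0.756; 0.0498 in the set-adjusted model; 0.00243 to 1 over 41 alternatives), and it overlaps 3 other annotated genes. Of 31 tested identity genes none passed over all genes or adjusted over the list alone (camera adjusted p = 0.93, median -0.089, mean 0.0015, opposite in sign); in the set-adjusted model 5 were higher, Il2ra and Ccr4 among them, and 2 lower, Gata3 and Ramp3. Of 21 tested type 2 cytokines and effectors none passed over all genes and 3 were higher adjusted over the list alone. Their median was 0.15 (set A 0.23, set B 0.13) and camera called the list higher (adjusted p = 0.0392; adjusted p = 0.606 with an estimated correlation). Of these, 6 were higher in the set-adjusted model: Il5, Il9 (1.24), Il10 (0.65), Calca (0.83), Penk and Vegfa (0.83).

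Metabolic and stress lists moved upward by smaller amounts. Glycolysis genes had a median of 0.31 (set A 0.31, set B 0.29), with 21 of 22 tested members above 0. Aldoc, a fructose-bisphosphate aldolase, rose from 8.57 ± 1.14 to 24.7 ± 2.89 CPM (log2 1.52, edgeR adjusted p = 0.00155) and was the 1 member past the threshold over all genes; 5 were higher adjusted over the list alone, and 13 in the set-adjusted model, among them the lactate transporter Slc16a3 (0.69) and Tpi1 (0.57). Camera gave an adjusted p of 5.43e-10, and adjusted p = 0.0553 with an estimated correlation. The list of the amino acid and integrated stress response, 38 tested genes, had a median of 0.26 (set A 0.29, set B 0.23; camera adjusted p = 6.69e-10; adjusted p = 0.00427 with an estimated correlation). Its pseudokinase Trib3 rose from 1.54 ± 0.262 to 3.88 ± 0.534 CPM (adjusted p = 0.0272; past in 26 of 39 alternatives, log2 0.65 to 1.45, adjusted p up to 0.33). Adjusted over the list alone 8 members were higher. In the set-adjusted model 16 were, among them asparagine synthetase Asns (0.63) and the cystine transporter Slc7a11 (1.44). Slc7a11 was low, at 0.693 ± 0.155 CPM in vehicle and 1.88 ± 0.156 in SC-57461A. It passed in 12 of 28 alternatives (log2 0.097 to 1.63, adjusted p up to 0.464). The p53 targets, 27 tested, had a median of 0.23 (set A 0.19, set B 0.20; adjusted p = 0.000371; adjusted p = 0.0451 with an estimated correlation). None of these passed singly in the pooled fit or adjusted over the list alone, and 9 did in the set-adjusted model, Cdkn1a (0.55) among them.

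Hypoxia response genes (20 tested, median 0.24, adjusted p = 0.000134), heat shock genes (21, 0.14, 0.000371), targets of the oxidative stress factor NRF2 (29, 0.093, 0.00564) and genes of the unfolded protein response (22, 0.11, 0.00928) were also called higher by camera. All 4 calls were lost with an estimated correlation (adjusted p = 0.0547, 0.0547, 0.0547 and 0.247). None of their members passed over all genes in the pooled fit. Adjusted over the list alone, 4, 0, 1 and 1 were higher, and in the set-adjusted model 7, 4, 8 and 3 were, such as Bnip3 (0.56), Hspd1 (0.39), Hmox1 (0.45) and the chaperone Hspa5 (0.35).

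Respiratory chain and ribosomal protein genes had larger medians in set A than in set B, a difference that was not tested. Nuclear-encoded oxidative phosphorylation genes had a median of 0.20 over 71 tested members (set A 0.28, set B 0.043), and cytosolic ribosomal proteins 0.24 over 78 (set A 0.31, set B 0.071). No member of either list passed over all genes or adjusted over the list alone. Camera called both higher (adjusted p = 0.0401 and 0.00558), and neither with an estimated correlation (adjusted p = 0.756 and 0.742). Without SC-57461A replicate 3, a set A library, both tests turned to the lower direction and were not called (adjusted p = 0.597 and 0.817; over all alternatives 7.41e-11 to 0.996 and 2.6e-13 to 0.817). That library drew 13.15% of its counts from transcripts shorter than 1 kb, the highest share of any library. The other set A libraries drew 10.9% to 11.4%. Whether this share accounts for the reversal, or for the larger medians in set A, was not tested. Tricarboxylic acid cycle genes had a median of 0.090 (set A 0.12, set B 0.011; camera adjusted p = 0.0392; adjusted p = 0.47 with an estimated correlation), and of 25 tested, cytosolic isocitrate dehydrogenase Idh1 alone was higher (8.59 ± 0.915 to 17.5 ± 0.798 CPM), also adjusted over the list alone. The 15 mitochondrially encoded genes had a median of 0.066 and were not called (adjusted p = 0.282).

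**Figure D5:**
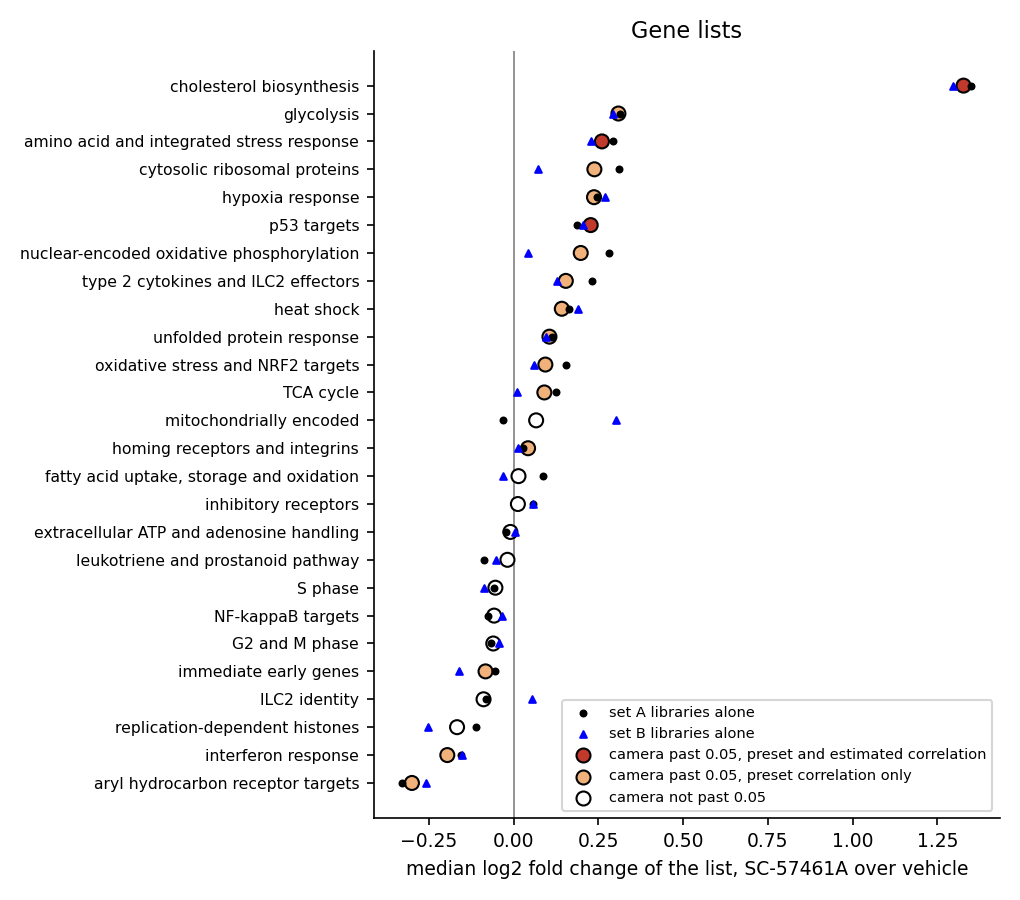
Large points give the median log2 fold change, SC-57461A over vehicle, of each gene list other than the cell type marker lists, coloured by whether camera passed an adjusted p of 0.05 with the preset and with the estimated correlation, and small points give the medians from set A or set B alone. Cholesterol biosynthesis lies at 1.33, and the lists with the next highest medians, glycolysis and the amino acid and integrated stress response, lie at 0.31 and 0.26.

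Homing receptors and integrins were called higher by camera (23 tested, median 0.042, adjusted p = 0.0204; adjusted p = 0.0929 with an estimated correlation), but not in the set-adjusted model (adjusted p = 0.0951; 0.00149 to 0.353 over 21 alternatives). The chemokine receptor Cxcr4 rose from 6.52 ± 0.688 to 12.2 ± 1.31 CPM (log2 0.91, edgeR adjusted p = 0.0253; past in 22 of 39 alternatives, log2 0.71 to 0.97, adjusted p up to 0.46), 5 members were higher adjusted over the list alone, and in the set-adjusted model the single genes Ccr4 (0.63), Ccr7 (0.88), Cxcr6 (0.40), Gpr183 (0.44) and S1pr1 (0.37) were higher too. Interferon response genes were called lower (34 tested, median -0.20; set A -0.16, set B -0.15; adjusted p = 0.0168; adjusted p = 0.47 with an estimated correlation). None of these passed singly over all genes or over the list alone; in the set-adjusted model 3 were lower, among them Zbp1 (-0.56), and 2 higher. The 7 tested targets of the aryl hydrocarbon receptor were called lower (median -0.30, adjusted p = 0.0401; adjusted p = 0.263 with an estimated correlation), with none past singly over all genes or over the list alone. NF-kappaB targets (22 tested, median -0.058, adjusted p = 0.436), inhibitory receptors (15, 0.012, 0.514), S phase genes (29, -0.054, 0.0837), genes of the G2 and M phases (33, -0.060, 0.152) and replication-dependent histones (18, -0.17, 0.118) were not called, and no member of them passed over all genes or adjusted over the list alone in the pooled fit. The set-adjusted model called S phase genes and histones lower (adjusted p = 0.0197 and 0.0323; 0.00864 to 0.547 over 21 alternatives and 0.00182 to 0.907 over 21 alternatives), and neither with an estimated correlation (adjusted p = 0.404 for both).

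Markers of other lymphocytes and of other intestinal cells were examined beside these lists. ILC3 markers were called higher (11 tested, median 0.38; set A 0.27, set B 0.45; adjusted p = 0.00162; adjusted p = 0.0547 with an estimated correlation). None passed singly over all genes, 3 were higher adjusted over the list alone, and in the set-adjusted model the cytokine genes Il17f (1.09), Il17a (0.75) and Il22 (0.59) and the receptor Cxcr6 were higher. ILC1 and NK cell markers (8 tested, median -0.091, adjusted p = 0.256) and T cell markers (12, 0.015, 0.294, mean -0.13, opposite in sign to the median) were not called by camera. Their most abundant members were granzyme B (Gzmb), at 5319 CPM in vehicle and 4724 in SC-57461A, and Zap70, at 149 and 134 CPM. Macrophage, monocyte and neutrophil markers (9 tested, median 0.075, adjusted p = 0.906) and stromal and endothelial markers (13, -0.58, 0.231) were not called. The mean of the former was -0.0098, opposite in sign to its median. Epithelial markers had a median of 1.12 over 9 tested and were called higher by camera in the set-adjusted model and not in the pooled fit (adjusted p = 0.0397 and 0.34, and 5.84e-05 to 0.885 over 20 alternatives). The set-adjusted call was lost with an estimated correlation (camera adjusted p = 0.483). None of the members of these 5 lists passed over all genes or adjusted over the list alone. Krt8, Krt19 and Muc2 were called higher in the set-adjusted model, and their counts lay mostly in the 2 SC-57461A libraries of set A. Mast cell, basophil and eosinophil markers had 3 tested members, too few for a test as a set, and none passed over all genes in the pooled fit. In the set-adjusted model Kit (-0.36, adjusted p = 0.0346) and Mcpt8 (-0.44, 0.044) were lower, and 3 of the 3 were lower adjusted over the list alone; Kit, the most abundant, was at 344 ± 94.4 and 273 ± 92.8 CPM.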

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

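The tests of RNA from other cells and of mislabelling as sources of the library sets, those of the sets and of other cells behind the sterol genes, and that of B cells behind Ighm were chosen only after the results were seen; that of other cells behind the sterol genes replaced one on the share of members called higher, its lymphocytes were later parted into 2 tests, that of mislabelling replaced one on sterol genes picked by the labels, and that of B cells replaced one on Igkc, Cd79a and Ms4a1 alone. The others were fixed after the data had been examined but before their own values were seen, though the counts of genes called with the length offset were known by then.

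A single library stood apart from the other 3 of its treatment in 5 of 134 groups of 4 examined, where chance would give 6.7. Scd1 was at 13.88 CPM in vehicle replicate 3 (others 11.81 to 12.02), and Mdh1 was at 435.4 CPM in vehicle replicate 2 (others 412.9 to 415.4) and at 598.5 CPM in SC-57461A replicate 3 (others 465.9 to 483.7). In SC-57461A replicate 2, Suclg2 was at 26.77 CPM (others 33.02 to 34.09) and Fosl2 at 127.2 CPM (others 102 to 105.1).

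Other splits of the 8 libraries into 4 and 4 were used to ask whether chance could give as much. For the 50 called genes chance cannot be excluded by the share of splits alone, 2 of 35, because the split by library set called 6797 genes, which points to a structure of the samples; from set A alone 122 genes were called and from set B alone 103. Among the 18 splits that part each set evenly the highest other count was 0. The same holds for the 29 terms (2 of 35 splits, 413 terms by library set). For the 18 gene lists 1 of 35 splits, the real one, gave as many (highest other 16), but these splits ignore the library sets. Splits with 0 called genes gave up to 16 lists, so this share does not exclude chance. Among the 18 splits that part each set evenly, too few for a share under 0.05, the highest other number of lists was 9 against 18, and with library set as a term 12 against 19. With library set as a term there are 18 splits, too few for a share under 0.05; the real count was 804 and the highest other 0, in 1 of 18 splits.

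The 2 library sets differed in 7634 genes, 3968 higher and 3666 lower in set A, far more than the treatments did. The set difference fell with transcript length (Spearman correlation across genes -0.38, genes not being independent replicates). The correlation with GC content was 0.0662, a test also made after the results were seen and then replaced by that of other-cell RNA. A trend with the longest annotated transcript, as fitted, is not the whole cause, since 81.19% of the 7634 genes still differed with a length offset. That offset does not see which transcripts were expressed, so a length bias that it missed is not excluded. Markers of other cell types were at low counts in set A (52 of 57 were higher there, with a summed 226 against 141 CPM). Dilution by traces of such RNA would barely lower the remaining genes. The genes called lower in set A were lower by a median of 0.4359 on the log2 scale, but the call itself keeps small differences out of that median, so its size decides nothing. That as many as 3666 genes were called lower argues against such RNA as the whole cause. Sets that were the true treatments, with labels arbitrary within them, are argued against as well: the fits of set A alone and of set B alone share no library, yet 66 genes were called in the same direction in both, where independent lists would share 0.571, and 0 in opposite directions. An exchange of the treatment for another unrecorded factor that the labels follow was not tested. Libraries made or cells sorted on 2 occasions, which the labels do not record, remain possible. No biological explanation other than RNA of other cell types was tested.

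The rise of cholesterol synthesis genes was present in either set (the lower median log2 fold change of the 2 was 1.295). It stayed at 1.346 with the length offset, so neither the sets nor the fitted trend with transcript length account for it. Myeloid, epithelial, stromal or endothelial cells in the treated cultures are argued against as well. Within set B the summed CPM of the sterol genes rose by 2593, while the summed markers of each of these lists fell (the smallest change was -0.05441% of the sterol rise). Members under 10 CPM in vehicle changed there by -1.41 (myeloid), -1.40 (epithelial) and -1.51 CPM (stromal and endothelial). A single member could still rise: in set B, Muc2 had 0 counts in vehicle and 2 to 14 in SC-57461A. Epithelial markers rose within set A (by 36.1 CPM), and 33.3% of those tested were called higher in the set-adjusted model. ILC1, NK or T cells are also argued against. Within set B the summed CPM of either list fell (changes of -537 and -14.7), and so did the sum of its members under 10 CPM in vehicle, where a high level in ILC2s cannot hide a rise (the smaller change was -0.0002125% of the sterol rise). ILC3s stay open. The summed CPM of the ILC3 list rose by 257, which is 11.09% of the rise of the sterol genes, and 36.4% of its tested members were called higher in the set-adjusted model, against none in the pooled fit; 209.6 CPM of that rise came from Cxcr6, abundant in vehicle too. Its members under 10 CPM in vehicle rose within set B by 3.67 CPM, only 0.142% of the sterol rise there. That is little, but a rise, unlike in the ILC1, NK and T cell lists. The treatment is a candidate explanation beside ILC3s, as a hypothesis; whether it acts through LTB4, through loss of the enzyme's activity or through another effect of the compound was not tested, since 1 compound at 1 time was used.

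Ighm rose in each treated library, from 3.06 to 4.45 CPM in vehicle to 21.1 to 22.9 CPM (scaled by library totals). B or plasma cells would bring their other abundant transcripts, but the 5 other tested markers, Cd79b by far the most abundant, changed together by 0.549 CPM while Ighm rose by 18.4 CPM (library set as a term). The upper 95% limit of that change was 16.8% of the Ighm rise, and Igkc had 0 counts in SC-57461A replicates 1 and 4. A candidate explanation is transcription of the unrearranged locus in ILC2s themselves, which gene-level counts cannot test.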

How the results depend on the processing

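Library set, set-alone, length-offset and protein-coding alternatives were chosen after the data were seen; the others were planned. All 25 called genes among those named kept their direction in up to 41 alternatives, and 10 passed in every one (Ighm, Scd1, Hmgcs1, Fads2, Msmo1, Idi1, Cyp51, Fdps, Mvd and Fdft1). Of the single-gene results, leaving out libraries aside, 1183 kept direction and side of the threshold, 67 fell short, 85 newly passed and 7 reversed. Leaving out 1 library in the pooled fit ended calls: Peg10 by each except SC-57461A replicate 3 (adjusted p up to 0.12), Sema4a by SC-57461A replicate 4 (adjusted p up to 0.0641), Egr1 by each except SC-57461A replicate 2 and SC-57461A replicate 3 (adjusted p up to 0.0904), Txnip by vehicle replicate 3, SC-57461A replicate 1, SC-57461A replicate 2, SC-57461A replicate 4 (adjusted p up to 0.0702), Scd2 by vehicle replicate 1, vehicle replicate 2, vehicle replicate 3 (adjusted p up to 0.0572), Acsl3 by any of the 8 (adjusted p up to 0.202), Trib3 by each except vehicle replicate 1 (adjusted p up to 0.137), Cxcr4 by each except SC-57461A replicate 3 (adjusted p up to 0.108). With library set as a term no library left out ended the call of any of these.

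Against 50 called genes, DESeq2 called 195, limma on FPKM 32 without a filter and 33 with a mean FPKM of at least 5, and a change of at least 1 left 33 by construction. Library set as a term gave 804, with the length offset 969, and with DESeq2 1504; set A alone gave 122 and set B alone 103. Leaving out 1 library gave 28 (without vehicle replicate 3) to 38 (without SC-57461A replicate 3), and 31, 31, 32 and 32 without vehicle replicates 1 and 2 and SC-57461A replicates 1 and 4. With library set as a term the 804 became 249 (without SC-57461A replicate 4) to 973 (without vehicle replicate 3), and 325, 262, 329, 422, 879 and 503 without vehicle replicates 1, 2 and 4 and SC-57461A replicates 1, 2 and 3. Such fits hold fewer libraries; the cause was not tested here or for the other counts. On counts simulated without library sets but with the spread of the pooled fit, edgeR recovered 1.52% of genes changed by 0.5 on the log2 scale. The pooled fit was not run on simulated counts that hold the library sets, so its recovery there is not known.

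Deviations of same-numbered libraries had correlations of -0.59, 0.63, -0.56 and 0.61, and not every library correlated best with its own number. These signs follow the library sets: replicates 2 and 4 share a set across the treatments, and replicates 1 and 3 do not. The check therefore cannot tell whether samples are paired by number beneath the sets. The replicate block gave 15 genes with edgeR and 13 with limma on FPKM, and 12 of the 25 called named genes passed; terms under the block were not run, since 15 calls are fewer than 20.

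Of 18 called lists, 3 held with an estimated correlation, also with library set as a term (3), and leaving out 1 library gave 12 to 17; 12 was without SC-57461A replicate 1. The fry test called 12 lists, 11 of those 18 and the leukotriene and prostanoid pathway list. With library set as a term it called 18, of which camera did not call 5 there: B and plasma cell markers; ILC1 and NK cell markers; fatty acid uptake, storage and oxidation; homing receptors and integrins; leukotriene and prostanoid pathway. The 29 terms became 143 with library set as a term, 137 with the length offset added, 28 with protein-coding genes only, 75 with both library set and protein-coding genes only, and 18 to 25 with 1 library left out (18 without vehicle replicate 3, 19 without vehicle replicate 1).

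Direction reversed in the following results, and the cause was not tested. Without SC-57461A replicate 3 the test turned for the list nuclear-encoded oxidative phosphorylation (adjusted p = 0.597; 1.03e-05 to 0.996 over the libraries left out), the list cytosolic ribosomal proteins (0.817; 6.64e-08 to 0.817) and the list epithelial markers (0.885; 0.00578 to 0.885; 0.632 in set B alone). None of these genes was called in the pooled fit: Lta4h turned in set A alone (0.030 on the log2 scale), Alox5ap in set B alone (-0.64), Ltb4r2 with library set and without SC-57461A replicate 4 (-0.053), Areg with quantile normalization (-0.00068), Panx1 without vehicle replicate 2 (-0.0069 to 0.16 over the libraries left out), and Il13 with array weights (-0.047) and without SC-57461A replicate 3 (-0.012 to 0.29). Jchain turned without vehicle replicate 2 (-1.08 to 0.37 over the libraries left out, and 0.10 with library set) and in set B alone (0.15). Cd79a turned with the replicate block (0.15), without vehicle replicate 2 (-1.03 to 0.031), with library set without vehicle replicate 3 (0.19) and in set B alone (0.39).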

Other observations

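The models with library set as a term and the genes named here were chosen only after results were seen; the lists of liver X receptor targets and lysosomal genes were drawn up after the data were examined and before their members were looked at, except Asah1, whose rise had been seen.

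With library set as a term, genes outside the fixed lists moved as well. The metallothioneins Mt1 and Mt2, which bind zinc and copper, were higher (log2 1.27 and 1.18, with 80.1 ± 39.1 and 204 ± 122 CPM for Mt1 in vehicle and SC-57461A, n = 4), and Mt1, which differed by 1.46 on the log2 scale between set A and set B, changed by 1.44 within set A and 1.09 within set B. The transferrin receptor Tfrc (0.66), the phosphatidate phosphatase Lpin1 (0.97), the sterol-regulated gene Tmem97 (0.88) and Enpp2, which makes lysophosphatidic acid (0.74), were higher too, with like changes in both sets (Tfrc 0.65 and 0.67, Enpp2 0.75 and 0.74). None of these passed without the library set. Spp1, the secreted phosphoprotein osteopontin, passed in both models, with 4.25 ± 0.396 and 7.78 ± 0.929 CPM in vehicle and SC-57461A.

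Among protein-coding genes alone, the terms over-represented in the higher genes of that model reached beyond sterols to the HIF-1 signaling pathway (16 of 89 tested genes, 2.67 by chance), the glycolytic process (8 of 21) and amino acid biosynthesis (8 of 23). The lower genes were enriched for actin binding (21 of 193 tested, 5.55 by chance) and the Rap1 signaling pathway (20 of 175), with one-sided Fisher's exact adjusted p of 0.000173 for either. When genes of any type were counted, 17 of the 19 higher genes of the GAIT complex term were processed pseudogenes, so that its call rests mostly on pseudogene copies. Genes called higher with library set as a term had a longest transcript with a median of 2487 bases and genes called lower 4150 bases, and the treatment effect fell with transcript length across genes (Spearman correlation -0.23; genes are not independent replicates).

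A candidate explanation for the rise of sterol synthesis is less sterol in the cells, which would lower the targets of the liver X receptor. Of 8 tested targets, the sterol exporters Abca1 (-0.79) and Abcg1 (-0.44) were called lower with library set as a term and none was called higher. Of the 8, 4 had a positive sign, with log2 changes up to 0.078 (Srebf1). The list did not pass the camera test of limma (adjusted p = 0.106 over both lists, 0.05283 unadjusted; the adjustment was added afterwards). The fry test, not the one planned here, put it lower (adjusted p = 0.0125 over both lists, and 0.0326 without the library set), so part of the evidence goes with this explanation and the planned test leaves it open. Accumulation of the compound in lysosomes, which could also hold back sterol, would raise lysosomal genes. Of 26 tested, 2 were higher (Npc2 0.36 and Asah1 0.66). That list did not pass camera of limma either (adjusted p = 0.472, 0.4719 unadjusted; fry adjusted p = 0.14), and this too stays open.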
